A study of Mus musculus with 9 samples.

How the data were processed

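RNA from mouse dendritic cells, grown from bone marrow progenitors, was measured on 9 Affymetrix mouse gene arrays in 3 groups of 3: wild-type cells left unstimulated, wild-type cells given LPS (bacterial lipopolysaccharide, the ligand of Toll-like receptor 4), and LPS-treated cells carrying a hairpin against JmjD2d. JmjD2d is the histone demethylase encoded by Kdm4d, which removes methyl groups from lysine 9 of histone H3. Per the labels' protocols, progenitors were kept in SCF, IL-3 and IL-6 at 20 ng/ml each. Dendritic cells then formed over 8 days, with 4% GM-CSF supernatant and 5 ng/ml SCF for 4 days and GM-CSF without SCF for a further 4 days. The hairpin came from a retrovirus and infected cells were selected in 2 mM histidinol, whereas the wild-type cells were untransduced. No array of a control hairpin and no array of unstimulated knockdown cells was analysed here. LPS was given at 100 ng/ml and RNA was taken after 4 h.

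The deposited values are on the log2 scale and were made by the authors with RMA (background correction, normalization between arrays and summary per probe set), per the submitters' processing notes, which give no version. The values fit that unit: array medians lay between 7.217 and 7.315, and the sorted values of the arrays differed from their mean by 0.029 on average. No further normalization was applied.

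Of 35556 deposited probe sets (called probes here), 23410 were in the platform's gene table. Of these, 21789 named a single gene and 1621 named several, and the 12146 deposited probes outside the gene table named none. Symbols were looked up through the Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, which matched 21698 of the single-gene probes, and 91 kept the platform's symbol. Each gene was represented by the single-gene probe with the highest mean over the 9 arrays, which gave 19938 genes, 999 of them with more than 1 probe. Probes that name several genes or none were left out of the comparisons.

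A linear model with a mean per group was fitted to the 9 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderated tests, and p-values were adjusted by the Benjamini-Hochberg method over the 19938 genes. An adjusted p under 0.05 is called a change. The tests are two-sided. The model had 6 residual degrees of freedom and the prior added 2.31. The comparisons were: LPS against no stimulation in wild-type cells, knockdown against wild-type cells after LPS, and LPS-treated knockdown against unstimulated wild-type cells. Errors given with a log2 difference are standard errors from this model. The share of a gene's LPS response that the knockdown cells kept is the third difference as a percent of the difference in wild-type cells. It is counted from unstimulated wild-type cells, so it does not measure an induction within knockdown cells.

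The labels number the replicates 1 to 3 in each group, and the design text speaks of independent cultures without saying that a number marks a shared culture. The deviations from the group means correlated across genes by 0.14 to 0.48 in all 9 pairs of arrays with the same number, and by -0.41 to 0.25 in pairs with different numbers, so the numbers were taken to pair the arrays. A fit with the replicate number as a block, planned as an alternative, is called the paired fit, and its value stands beside a result where it changes a call or moves a count by more than 1.5 times.

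The comparisons, the rule for named genes, 27 gene lists with 558 members (514 measured) and the alternatives were chosen before the data were examined. The lists were the Kdm4 family, H3K9 methylation regulators, inflammatory cytokines, chemokines, type I interferon response, NF-kB feedback and signalling, immediate-early and AP-1 genes, dendritic cell maturation, MHC class II presentation, MHC class I presentation, inflammatory effectors, pattern recognition receptors, cell cycle, cholesterol synthesis, glycolysis and hypoxia, lysosome, ATF4 amino acid stress, p53 targets, reference genes, and markers of macrophages, dendritic cells, plasmacytoid dendritic cells, neutrophils and granulocyte precursors, mast cells and basophils, hematopoietic progenitors, erythroid cells and megakaryocytes, and lymphocytes. A list was tested as a set against all other genes with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists, and again with a correlation estimated per list and with fry, a rotation test of a list's net direction that makes no comparison with other genes. Counts of changed members are given over all genes and adjusted over the list alone.

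The rule named Kdm4d, the 10 genes with the largest log2 difference in each direction among changed genes whose 3 values did not overlap those of the other group, up to 4 members of each list with the smallest p, and the 10 LPS-induced genes lower in the knockdown that kept the smallest share of their induction. Unnamed loci were passed over. Genes named outside the rule are marked as chosen after their values were seen.

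The alternatives were the paired fit, a fit on only the groups compared, a trended and robust prior, weights per array, quantile normalization, centring on array medians, leaving out dim genes (highest group mean under the 40th percentile of all values, 6.74), testing all 35556 probes, averaging a gene's probes, leaving out each array in turn, a minimum of 2-fold for changes and of 4-fold for induction, adjustment over the induced genes alone, and the other set tests. The model was tested on simulated data made from the real group means and spreads of the 19938 genes. In the simulated LPS comparison it recovered 61.2% of 67 genes changed by a log2 of 0.5, 86.6% of 67 changed by 1 and 98.5% of 66 changed by 2, with 4 false calls. In the simulated knockdown comparison it recovered 49.3%, 85.1% and 97% of as many genes, with 10 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.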

Results

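The 9 arrays measured gene expression in wild-type dendritic cells before and 4 h after LPS, and in JmjD2d-knockdown dendritic cells 4 h after LPS, with 3 arrays per group. Replicates of a group correlated by 0.985 to 0.997 across genes, which are not independent of each other. Principal component 1 held 48.1% of the variance and separated the 3 unstimulated arrays, at -46.7 to -25.6, from the 6 LPS-treated arrays, at 12.6 to 25.4. Component 2 held 21.9%, and on it the knockdown arrays (2.6, 38.4 and 9.6 for replicates 1 to 3) lay above the wild-type LPS array of the same number (-30.2, 4.3 and -23).

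Kdm4d, the gene targeted by the hairpin, was measured by a single probe with a mean log2 value of 7.69 in wild-type cells after LPS and 7.31 in knockdown cells after LPS (n = 3 each). The knockdown value was 77.1% of the wild-type LPS value, a log2 difference of -0.37 (SE 0.13, 95% confidence interval -0.68 to -0.07) that did not pass the adjusted test (limma adjusted p = 0.278). It was below the wild-type LPS array of the same number in all 3 pairs, by log2 differences of -0.36, -0.43 and -0.34. The other Kdm4 demethylases differed by less: Kdm4a by -0.20, Kdm4b by -0.08 and Kdm4c by 0.13 (adjusted p from 0.571 to 0.703). None of the 4 family members changed between knockdown and wild-type cells (camera adjusted p = 0.258 for the family), and limma counted 1, Kdm4d, at an unadjusted p under 0.05. After LPS in wild-type cells Kdm4a rose by 0.50 (SE 0.13, adjusted p = 0.0496) and Kdm4d had a difference of 0.19 (adjusted p = 0.402).

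**Figure D1:**
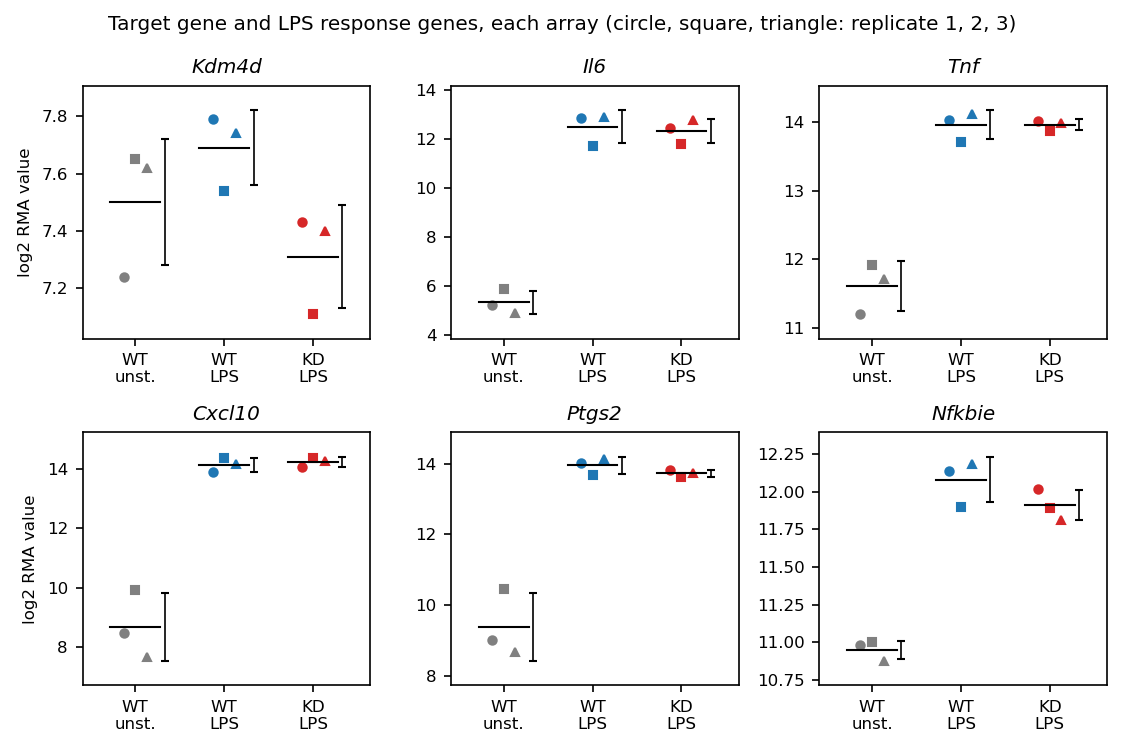
Log2 values (y axis) of Kdm4d and 5 LPS response genes in each of the 9 arrays, by group; markers show replicates 1, 2 and 3, the line the group mean and the bar its SD (n = 3). Kdm4d means lie between 7.31 and 7.69, whereas Il6 goes from 5.32 in unstimulated to 12.5 in LPS-treated wild-type cells and 12.33 in knockdown cells.

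The first comparison asks how wild-type dendritic cells responded to LPS. Il6, an inflammatory cytokine, rose 145-fold (log2 difference 7.18, SE 0.39, n = 3 against 3, adjusted p = 0.00019). Il12b, the shared subunit of the cytokines IL-12 and IL-23, rose 77.1-fold (6.27, SE 0.40, adjusted p = 0.000229). Cxcl10, a chemokine for activated T cells, rose 43.3-fold (5.44, SE 0.47). Ptgs2, the inducible enzyme of prostaglandin synthesis, rose 23.6-fold (4.56, SE 0.40). Ccr2, the chemokine receptor of monocytes, fell 5.32-fold (-2.41, SE 0.50, adjusted p = 0.0198). Sesn1, a stress-responsive p53 target, fell 4.7-fold (-2.23, SE 0.33, adjusted p = 0.00522). Across the 19938 genes, 796 rose and 1368 fell, 10.9% of those tested. Of these, 295 rose and 240 fell by at least 2-fold, and 81 rose and 16 fell by at least 4-fold.

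The other genes with the largest rises were Ifi205, an interferon-inducible gene (log2 difference 5.46), the neutrophil-attracting chemokines Cxcl2 (4.94) and Cxcl3 (4.71), Tnfsf15, a cytokine of the TNF superfamily (4.90), and the antiviral effectors Ifit2 (4.67) and Rsad2 (4.33). Their standard errors were 0.44 to 0.85. The other large falls were those of Arrdc3, an arrestin-family adaptor (-2.53), Scel (-2.50), Cables1 (-2.49), and Cnr2, a cannabinoid receptor (-2.40). Further falls were those of Eps8, an actin regulator (-2.35), Lpin1, a phosphatidate phosphatase (-2.29), Sh2d1b1, an adaptor of SLAM-family receptors (-2.28), and Kcne3, a potassium channel subunit (-2.16).

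Of 28 measured genes of NF-kB feedback and signalling 24 rose, and 28 when adjusted over the list alone (camera adjusted p = 2.5e-24, adjusted p = 0.138 with an estimated correlation). Tnfaip3, a brake on NF-kB signalling, rose by a log2 of 2.68 (SE 0.19). Cflar, an inhibitor of caspase activation, rose by 1.72 (SE 0.08), and Icam1, an adhesion molecule, by 1.60 (SE 0.08). Inflammatory cytokines rose in 12 of 23 members (19 adjusted over the list alone, camera adjusted p = 1.08e-11, adjusted p = 0.138 with an estimated correlation), among them Tnf by 2.35 (SE 0.18) and Il27 by 2.53 (SE 0.22). Chemokines rose in 9 of 21 members (11 adjusted over the list alone, camera adjusted p = 5.82e-08, adjusted p = 0.12 with an estimated correlation), with Ccl4 at 3.83 (SE 0.11) and Cxcl9 at 2.56 (SE 0.31). Inflammatory effectors rose in 16 of 24 members (24 adjusted over the list alone, camera adjusted p = 3.2e-14, adjusted p = 0.138 with an estimated correlation), including Met, a receptor tyrosine kinase, by 1.85 and Ch25h, which makes 25-hydroxycholesterol, by 2.25.

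Type I interferon response genes rose in 17 of 35 members (25 adjusted over the list alone, camera adjusted p = 3.2e-14, adjusted p = 0.395 with an estimated correlation), and in 31 of 35 in the paired fit. Gbp5, a guanylate-binding protein, rose by 3.99 (SE 0.23), Ifih1, a sensor of viral RNA, by 2.28 (SE 0.19), Parp14 by 1.88 (SE 0.14) and Irf1, an interferon regulatory factor, by 1.64 (SE 0.11), although a second and dimmer probe of Irf1 read 0.26 (adjusted p = 0.0853 among all probes). The interferon list's mean was higher in arrays numbered 2 than in the other replicates of the same group, by 1.13 in unstimulated wild-type, 1.31 in LPS-treated wild-type and 0.67 in knockdown cells. Dendritic cell maturation genes rose in 12 of 20 members, also when adjusted over the list alone (camera adjusted p = 2.79e-08, adjusted p = 0.0515 with an estimated correlation): the costimulatory receptor Cd40 by 4.25 (SE 0.38), Fscn1, the actin bundler of dendrites, by 2.56 (SE 0.33), Marcksl1 by 2.24 (SE 0.16) and Slamf1 by 0.86 (SE 0.10). MHC class I presentation genes rose in 7 of 13 members, the same number adjusted over the list alone (camera adjusted p = 0.00149, adjusted p = 0.395 with an estimated correlation), with Tap1, a peptide transporter subunit, at 1.36 and its partner Tap2 at 0.73. The class I heavy chains of this list, H2-K1, H2-D1, H2-T23 and H2-Q7, were not among the measured members. Lysosome genes fell as a list with 2 of 20 members called, also over the list alone, Npc1 at -0.41 and Hexa at -0.33 (camera adjusted p = 0.000248, adjusted p = 0.266 with an estimated correlation).

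The 19 other lists were not called as sets by camera. Fry called some of them: reference genes lower (fry adjusted p = 0.00143), and pattern recognition receptors (0.0138) and plasmacytoid dendritic cell markers (0.0267) higher. Pattern recognition receptors (camera adjusted p = 0.092) had 6 of 23 members higher, such as Nod2 (1.26), Nlrp3 (1.74) and Tlr2 (1.39), and 1 lower, Tlr13 (-0.55). Over the list alone 6 were higher and 2 lower, and 3 were lower in the paired fit. Immediate-early and AP-1 genes (adjusted p = 0.324) had 3 of 22 higher, Maff (2.36), Atf3 (0.93) and Junb (0.67), and 3 lower, including Fos (-0.79), against 4 and 4 over the list alone. The p53 targets (adjusted p = 0.312) had 3 of 17 higher, including Fas (1.90) and Plk2 (2.33), and 5 lower, including Trp53inp1 (-1.89). Over the list alone 5 were higher and 6 lower, and 5 were higher in the paired fit. Cell cycle genes (adjusted p = 0.312) had 2 of 28 higher, Mki67 (2.36) and Tyms (0.95), also over the list alone, and the paired fit added Rrm1 as lower (-0.84).

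Among H3K9 methylation regulators (camera adjusted p = 0.314) 2 of 17 fell, the methyltransferase Setdb1 by -0.75 and Cbx3, a heterochromatin protein, by -1.02. Over the list alone 3 rose and 5 fell. Cbx5, another heterochromatin protein, was at -0.71 (adjusted p = 0.053, and 0.0262 in the paired fit), and Kdm6b, a demethylase of lysine 27 of histone H3 that the list also holds, at 1.07 (adjusted p = 0.0691, and 0.0359 in the paired fit). Cholesterol synthesis (adjusted p = 0.312, and 0.0401 in the paired fit, higher, but adjusted p = 0.569 there with an estimated correlation) had 1 of 19 higher, Idi1 (0.94), and 2 lower, Dhcr7 (-1.21) and Ebp (-0.44). Over the list alone 2 were higher and 2 lower, and 7 were higher in the paired fit. Glycolysis and hypoxia (adjusted p = 0.138) had 3 of 20 higher, including Hk2 (0.97), and 5 over the list alone and in the paired fit. ATF4 amino acid stress (adjusted p = 0.71) had 3 of 23 higher and 3 lower, among them Slc3a2 (0.46) and Aldh18a1 (-0.96), and 5 and 4 over the list alone. MHC class II presentation (adjusted p = 0.674) and reference genes (adjusted p = 0.121) had 0 called members of 12 and 10 by limma, with 0 and 2 lower at an unadjusted p under 0.05 and 0 over the list alone. The paired fit called H2-DMa (-0.48) and Sdha (-0.34) lower in these lists. The Kdm4 family had an adjusted p of 0.319.

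Among the cell type markers, those of neutrophils and granulocyte precursors had 1 of 20 members higher, Csf3r at 0.95 (camera adjusted p = 0.0897, and 0.00118 in the paired fit, higher, but adjusted p = 0.528 there with an estimated correlation). Those of mast cells and basophils had 2 of 19 higher, Hdc, the histamine-making enzyme, at 3.23 and Il13 at 0.53 (adjusted p = 0.121). Macrophage markers (adjusted p = 0.319) had 2 of 20 higher, Cx3cr1 (1.26) and Vcam1 (1.33), and 2 lower, Ccr2 and Trem2 (-0.39). Plasmacytoid dendritic cell markers (adjusted p = 0.195) had 1 of 9 higher, Ccr9 at 0.47, and erythroid and megakaryocyte markers (adjusted p = 0.175) 1 of 12, Car2 at 2.04. In these 5 lists the counts over the list alone were the same. Dendritic cell markers (adjusted p = 0.328) had 1 of 19 lower, Cd24a at -0.48, and hematopoietic progenitor markers (adjusted p = 0.752) 1 of 19 lower, Sox4 at -0.86, and 0 in either over the list alone. The paired fit called 3 lower in each, among them Kit at -1.03 (adjusted p = 0.104, and 0.0236 in the paired fit), which is also a mast cell marker. Lymphocyte markers (adjusted p = 0.374) had 0 of 17 called by limma, with 1 higher and 1 lower at an unadjusted p under 0.05. The LPS counts depended on single arrays: 393 rose and 544 fell without unstimulated replicate 3, and 1246 and 2178 without LPS replicate 2.

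**Figure D2:**
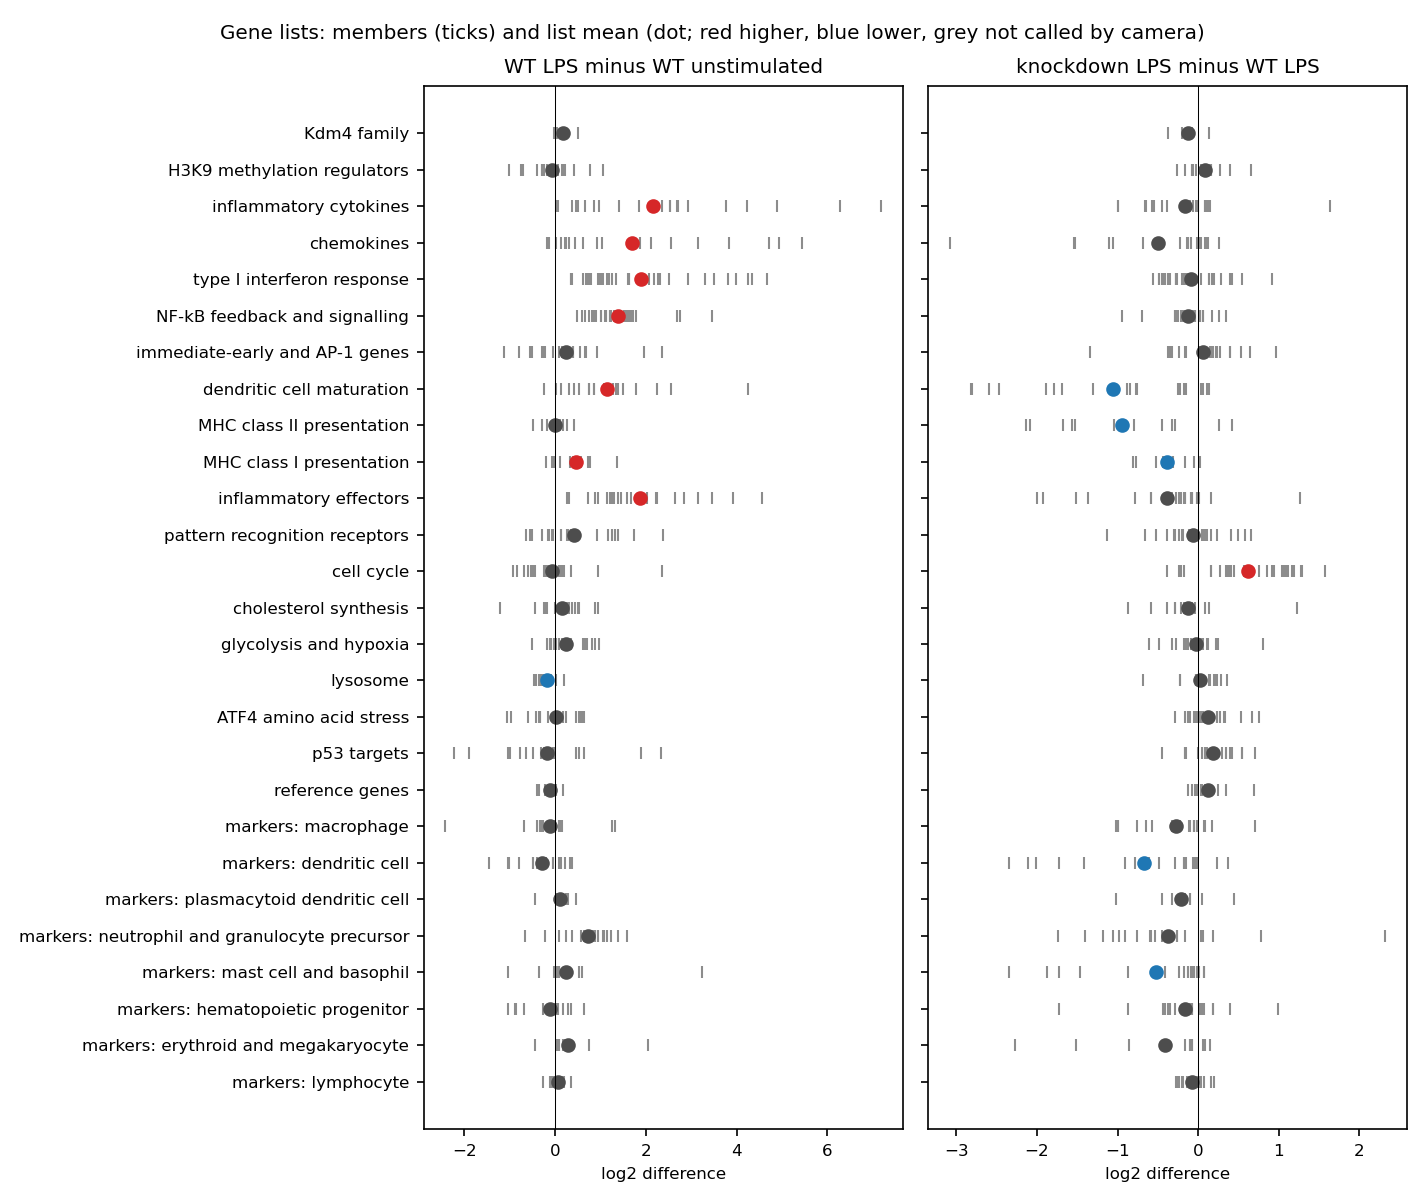
Log2 differences (x axis) of the members of each of the 27 gene lists (ticks) and the list mean (dot) for LPS in wild-type cells, left, and knockdown against wild-type cells after LPS, right; red dots mark lists higher and blue dots lists lower by camera at the preset correlation. The mean of the dendritic cell maturation list is 1.15 on the left and -1.05 on the right, and that of NF-kB feedback and signalling is 1.39 and -0.13.

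The second comparison, the one the series title names, asks which genes differ between JmjD2d-knockdown and wild-type cells after LPS. It cannot separate loss of JmjD2d from infection and selection, which only the knockdown cells had. In knockdown cells Cd86, a costimulatory ligand for T cells, was 5.56-fold lower than in wild-type cells (log2 difference -2.47, SE 0.25, n = 3 against 3, limma adjusted p = 0.00929). Ccr4, a chemokine receptor, was 6.18-fold lower (-2.63, SE 0.29, adjusted p = 0.012). The gap junction protein Gja5 was 5.59-fold lower (-2.48, SE 0.21, adjusted p = 0.00748). Pparg, a nuclear receptor of lipid metabolism, was 4.77-fold higher (2.25, SE 0.18, adjusted p = 0.00673), and Spic, a transcription factor of red pulp macrophages, was 6.67-fold higher (2.74, SE 0.44, adjusted p = 0.0384). In all, 80 genes were higher and 72 lower, 0.762% of those tested, 22 and 31 of them by at least 2-fold. The paired fit called 301 higher and 247 lower, among them all 152.

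The other genes with the largest falls included Il2ra, a subunit of the IL-2 receptor (-2.99, SE 0.51), Pdcd1lg2, a ligand of the inhibitory receptor PD-1 (-2.82, SE 0.47), and Il21r, the IL-21 receptor (-2.63, SE 0.41). They also included Antxr1, an anthrax toxin receptor (-2.44, SE 0.30), Tmem176b (-2.37, SE 0.34), Ppbp, a platelet chemokine (-2.27, SE 0.37), and Stat4, a transcription factor of cytokine signalling (-2.14, SE 0.32). The other large rises were those of Sh2d1b1 (2.32, SE 0.29), which LPS had lowered by 2.28 in wild-type cells, Slc16a9, a monocarboxylate transporter (2.06, SE 0.33, although its second and dimmer probe read 0.11), and Csn2, a casein (2.04, SE 0.35). Others were those of Nrg4, a growth factor (1.76, SE 0.24), Maoa, an amine oxidase (1.66, SE 0.15), Myo6, a myosin motor (1.65, SE 0.17), Mreg (1.64, SE 0.27) and Il18, an inflammatory cytokine (1.64, SE 0.26). Of the 72 lower genes, 52 had all 3 knockdown values below all 6 wild-type values, and of the 80 higher genes 60 had all 3 above. Chance places 3 of 9 values so in 1.19% of orders, and these genes were selected for their difference.

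**Figure D3:**
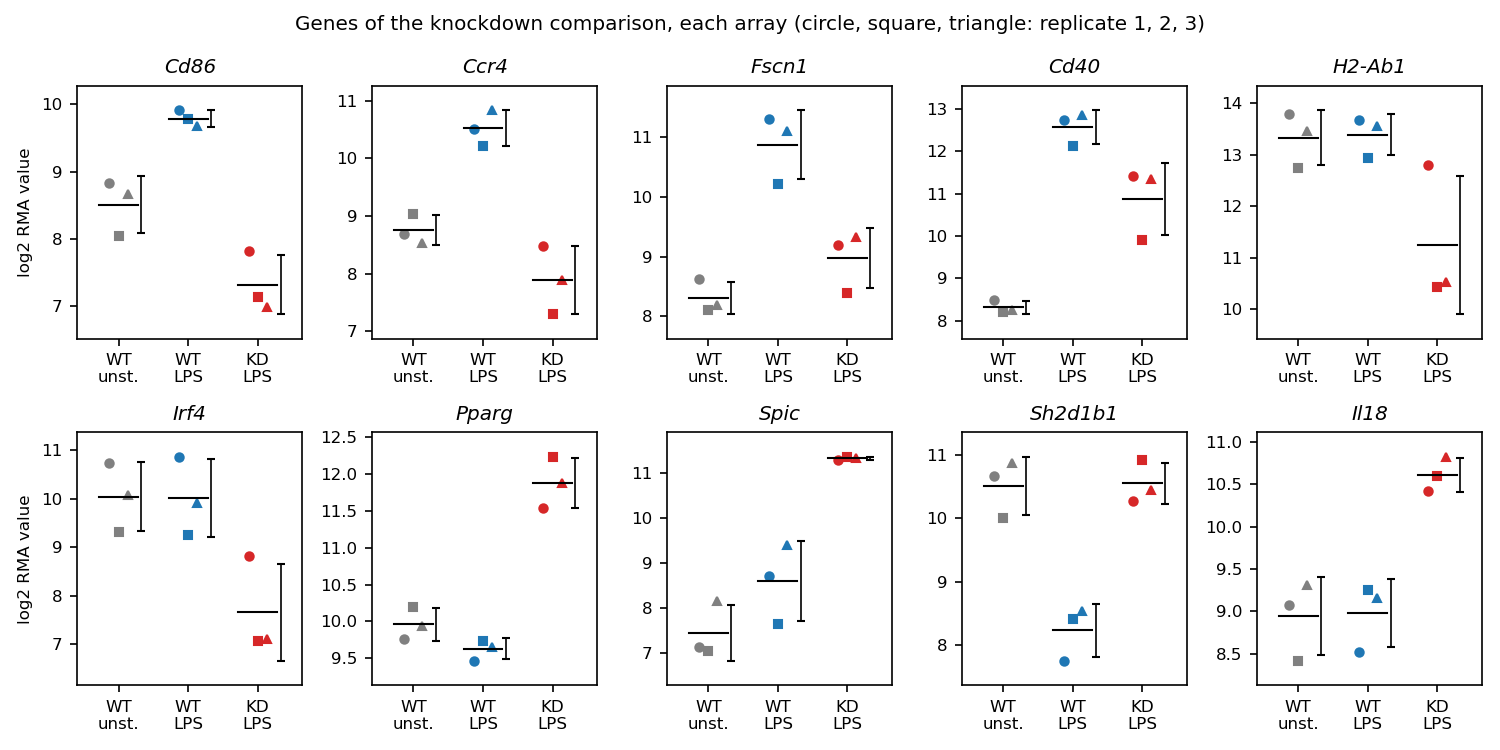
Log2 values (y axis) of 10 genes of the knockdown comparison in each array, by group; markers show replicates 1, 2 and 3, the line the group mean and the bar its SD (n = 3). Cd86 has means of 8.51, 9.79 and 7.32 in unstimulated, LPS-treated and knockdown LPS-treated cells, and Pparg 9.96, 9.63 and 11.88; Cd40, H2-Ab1 and Irf4 passed the test in the paired fit alone.

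Dendritic cell maturation genes fell as a list in the knockdown cells. Of 20 measured members 6 fell, 11 when adjusted over the list alone and 9 in the paired fit, and none rose (camera adjusted p = 1.02e-07, adjusted p = 0.0545 with an estimated correlation, fry adjusted p = 0.00121). Besides Cd86 and Pdcd1lg2 these were Fscn1 (-1.89, SE 0.33), Socs2, a brake on cytokine signalling (-1.31, SE 0.22), Slamf1 (-0.85, SE 0.10) and Cd80, the second costimulatory ligand (-0.76, SE 0.12). The 3 that the paired fit adds, named after their values were seen, are Ccr7, the receptor that guides mature dendritic cells to lymph nodes (-2.81, adjusted p = 0.0815, and 0.0111 in the paired fit), Cd83 (-1.79, adjusted p = 0.106, paired 0.0103) and Cd40 (-1.69, adjusted p = 0.0971, paired 0.0259).

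Antigen presentation genes were lower as lists by camera at the preset correlation. Fry called neither the MHC class II nor the MHC class I list (fry adjusted p = 0.0757 for each). MHC class II presentation genes were lower (camera adjusted p = 0.00126, adjusted p = 0.42 with an estimated correlation), with 0 of 12 members called by limma over all genes, 9 lower and 1 higher at an unadjusted p under 0.05, and 7 lower and 1 higher adjusted over the list alone. The differences were -2.14 for H2-Ab1 (SE 0.60, adjusted p = 0.158, and 0.0433 in the paired fit), -2.09 for H2-Eb1 (SE 0.53, adjusted p = 0.125, paired 0.032) and -1.57 for H2-Ob (SE 0.45, adjusted p = 0.171, paired 0.0442), and the paired fit called 5 members lower. MHC class I presentation genes, measured without the class I heavy chains, were lower (camera adjusted p = 7.62e-06, adjusted p = 0.42 with an estimated correlation), again with 0 of 13 called, 8 lower at an unadjusted p under 0.05 and 5 adjusted over the list alone. Psmb8, an immunoproteasome subunit, had a difference of -0.77 (adjusted p = 0.059, and 0.0205 in the paired fit).

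Markers of dendritic cells were lower as a list (camera adjusted p = 0.00178, adjusted p = 0.511 with an estimated correlation, fry adjusted p = 0.241), with 0 of 19 called, 6 lower and 1 higher at an unadjusted p under 0.05, and 5 lower and 1 higher adjusted over the list alone. The paired fit called 4: the receptor tyrosine kinase Kit (-1.73, adjusted p = 0.0729, and 0.017 in the paired fit) and the transcription factors Irf8 (-0.91, adjusted p = 0.091, paired 0.0201), Batf3 (-0.61, adjusted p = 0.108, paired 0.0435) and Irf4 (-2.34, adjusted p = 0.124, paired 0.00601). Markers of mast cells and basophils were also lower (camera adjusted p = 0.000872, adjusted p = 0.42 with an estimated correlation, fry adjusted p = 0.0757, and 0.0475 in the paired fit), with 0 of 19 called, 7 lower at an unadjusted p under 0.05, 4 adjusted over the list alone and 4 in the paired fit. Of the 19, 2, Kit and Gata2, are in other lists as well. Hdc had a difference of -2.34 (adjusted p = 0.0902) and Gata2, a transcription factor of mast cells and progenitors, of -0.87 (adjusted p = 0.0593, and 0.0306 in the paired fit). Cell cycle genes were higher as a list (camera adjusted p = 4.19e-08, adjusted p = 0.42 with an estimated correlation, fry adjusted p = 0.245), with 0 of 28 called, 13 higher and 1 lower at an unadjusted p under 0.05, and 5 higher adjusted over the list alone. The paired fit called 9, such as Rrm1, a ribonucleotide reductase subunit (1.17, adjusted p = 0.0729, paired 0.0123), Bub1b, a spindle checkpoint kinase (1.29, adjusted p = 0.142, paired 0.0354) and Cdk1, the mitotic kinase (0.75, adjusted p = 0.121, paired 0.0369).

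In other lists of the LPS response, 0 or 1 members passed the test in the knockdown comparison. NF-kB feedback and signalling had 0 of 28 members called, with 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.118), and the type I interferon response 0 of 35 by limma, with 1 lower (adjusted p = 0.421), and both 0 over the list alone. Inflammatory cytokines had 1 of 23 called, Il18, higher, and 1 higher and 1 lower over the list alone (list adjusted p = 0.258), and Il6 (-0.17), Tnf (0.00) and Il12b (-0.57) had adjusted p of 0.595 or above. Chemokines had 1 of 21 called, Cx3cl1, lower by -1.54 (SE 0.24, adjusted p = 0.0374), and the list had an adjusted p of 0.0517 (0.0221 in the paired fit, lower, but adjusted p = 0.514 there with an estimated correlation) with 5 members lower over the list alone. Ccl22, a ligand of Ccr4, had the largest difference of the list at -3.08, with an SE of 0.71 (adjusted p = 0.103). Inflammatory effectors had 0 of 24 called by limma, with 1 higher and 5 lower at an unadjusted p under 0.05 and 1 higher over the list alone (camera adjusted p = 0.0825, and 0.0347 in the paired fit, lower, but adjusted p = 0.667 there with an estimated correlation). Edn1, the vasoconstrictor endothelin, had a difference of -1.92 (adjusted p = 0.137, and 0.0442 in the paired fit) and Ch25h of 1.26 (adjusted p = 0.0753, paired 0.0215). Immediate-early and AP-1 genes had 1 of 22 called, Fos, higher by 0.97 (SE 0.13, adjusted p = 0.0198, list 0.14), and pattern recognition receptors 0 of 23, with 1 higher and 2 lower at an unadjusted p under 0.05 (adjusted p = 0.644).

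Of the remaining lists, reference genes had 1 of 10 called, Hprt, higher by 0.69 (SE 0.12, adjusted p = 0.0476, list 0.118), and erythroid and megakaryocyte markers 1 of 12, Ppbp, lower (list adjusted p = 0.0825). None was called by limma in cholesterol synthesis (camera adjusted p = 0.14, and 0.0221 in the paired fit, lower), neutrophil and granulocyte precursor markers (0.0732, and 0.0136 in the paired fit, lower), ATF4 amino acid stress (0.0732), p53 targets (0.0732), lysosome (0.118), H3K9 methylation regulators (0.118), macrophage markers (0.118), plasmacytoid dendritic cell markers (0.14), hematopoietic progenitor markers (0.14), lymphocyte markers (0.346) or glycolysis and hypoxia (0.946). With an estimated correlation the paired calls of cholesterol synthesis and of neutrophil markers are lost (adjusted p = 0.554 for each). In these 11 lists 0 to 4 members per direction had an unadjusted p under 0.05. Adjusted over the list alone, 4 progenitor, 3 macrophage and 2 neutrophil markers were lower, and 2 ATF4 genes and 1 cholesterol synthesis gene were higher. The paired fit called 2 progenitor markers, Kit and Gata2, lower. The direction of Dhcr7, the last enzyme of cholesterol synthesis, was opposite to that of its list, at 1.22 (adjusted p = 0.0699, and 0.0435 in the paired fit), and Mpo, the neutrophil peroxidase, was at -1.74 (adjusted p = 0.0825, and 0.032 in the paired fit).

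The knockdown counts depended on single arrays, with 11 higher and 7 lower genes without wild-type LPS replicate 3 and 257 and 126 without wild-type LPS replicate 2. Pparg, Maoa, Myo6 and Gja5 were the 4 of 33 named changed genes that passed in all their 19 alternative runs, at adjusted p of up to 0.0499. Cd86 had an adjusted p of 0.0557 without wild-type LPS replicate 1 and 0.0521 without replicate 3. Because no unstimulated knockdown array was analysed here, a difference after LPS cannot be divided into one present before LPS and one in the response to it.

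**Figure D4:**
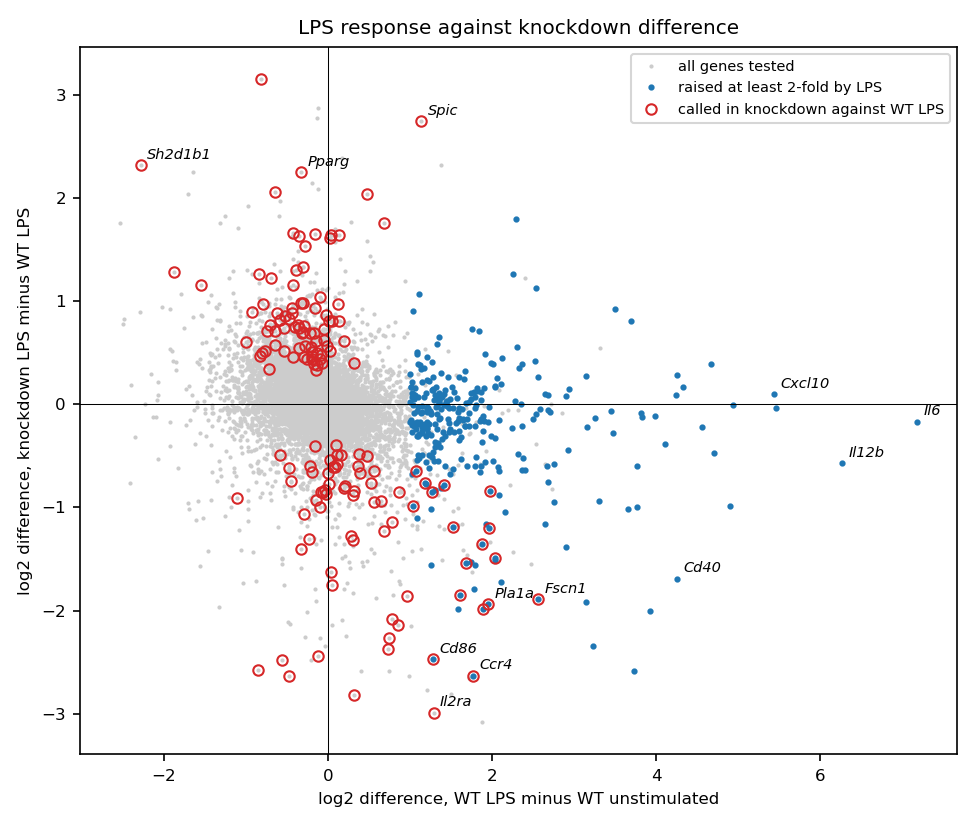
Log2 difference after LPS in wild-type cells (x axis) against the log2 difference of knockdown from wild-type cells after LPS (y axis) for each of the 19938 genes; blue points rose at least 2-fold with LPS and red circles changed in the knockdown. Il6 lies at 7.18 and -0.17, and Cd86 at 1.28 and -2.47; both axes use the same wild-type LPS arrays.

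Of the 295 genes that rose at least 2-fold with LPS in wild-type cells, 17 were lower in the knockdown and 0 higher by limma. Single arrays moved the 17 to 2 without wild-type LPS replicate 3, 3 without replicate 1 and 35 without replicate 2. At an unadjusted p under 0.05 there were 60 and 10, adjusted over the list alone 36 and 7, and in the paired fit 37 and 5 of 347. In the knockdown cells 237 were still higher than in unstimulated wild-type cells. Counted from the level of unstimulated wild-type cells, the median gene kept 91.9% of its induction (quartiles 72.5% and 105%). The medians were 90%, 96% and 93.1% in replicates 1, 2 and 3 (SD 2.97). Simulated sets of unchanged knockdown arrays (100), which share the wild-type LPS arrays that chose the genes, gave a median of 96.65% (94.16% to 98.45%). In the knockdown 35 genes kept less than 50%, against 8 (0 to 16) in the simulated sets, which each had their own induced genes (median 353, 326 to 373). Members of the NF-kB list that rose with LPS kept a median of 95.1% (24 genes), cytokines 96.8% (12), chemokines 96.9% (9) and interferon genes 94% (17), each within its range over the simulated sets (NF-kB 91.6% to 107%). The 12 maturation genes kept 48.2% (simulated 85.9% to 114%) and 7 MHC class I presentation genes 34% (simulated 78% to 117%). In the simulated sets noise was drawn independently for each gene and array, without the pairing of arrays. Genes of a list vary together in the real arrays (estimated correlation 0.025 for the maturation, 0.303 for the MHC class I and 0.434 for the NF-kB list). The simulated ranges, most of all those of lists, may therefore be too narrow. The observed group means, with the chance that helped choose the genes, were taken as true. The simulated medians of the share kept may therefore be too high. Of the 240 genes lowered at least 2-fold by LPS, 3 were higher in the knockdown and 1 lower (24 and 3 adjusted over the list alone, 14 and 4 of 273 in the paired fit), and the median kept was 88%, against 93.38% (90.2% to 97.52%) in the simulated sets.

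Among the LPS-induced genes lower in the knockdown, Cd86 had the smallest share kept (-93.3%), its knockdown value lying below that of unstimulated wild-type cells. It was followed by Ccr4 (-48.9%), the transcription factor Zeb1 (-14.9%), Sema7a, a membrane-anchored semaphorin (-5.29%), and Pla1a, a phospholipase (0.396%). Next were Rapgef2, an activator of Rap (4.87%), Cx3cl1 (8.77%), Tdgf1 (21.6%), Fscn1 (26.2%) and Pdgfrb, a growth factor receptor (27%). Among the 10, the differences from wild-type LPS cells ran from -0.99 for Rapgef2 to -2.63 for Ccr4. Whether these genes were already lower in knockdown cells before LPS was not measured, so a small or negative share need not be a lost response.

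Of the 72 genes lower in the knockdown, 28 had risen with LPS in wild-type cells, 4 had fallen and 40 were not called. Of the 80 higher genes, 28 had fallen with LPS, 1 had risen and 51 were not called. Independent lists of these sizes would share 2.87 (lower and risen), 4.94 (lower and fallen), 5.49 (higher and fallen) and 3.19 (higher and risen). The comparisons share the wild-type LPS arrays, so chance in those arrays moves them in opposite directions. The 100 simulated sets of unchanged knockdown arrays gave a median of 0 (highest 1) for lower and risen and 0 (highest 1) for higher and fallen. These sets had 0 knockdown calls in all (highest 1), so their overlap could not be larger and does not measure what the shared arrays add among real calls. Across genes, which are not independent replicates, the differences correlated by -0.31 (simulated median -0.19, range -0.23 to -0.14) with a covariance of -0.0372 (simulated -0.0149). Part of the excess over independent lists may come from the shared arrays, which are too few to be split into groups of 2. The simulated covariance already holds this sharing, and the observed one lay beyond its range (-0.01897 to -0.0107). Noise in those sets was independent between genes, so that range may be too narrow to tell the rest from sharing.

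The third comparison sets LPS-treated knockdown cells against unstimulated wild-type cells. Il6 was higher by a log2 of 7.01 (SE 0.39, n = 3 against 3, adjusted p = 0.000138), Il12b by 5.70 (SE 0.40), Cxcl10 by 5.53 (SE 0.47), Ptgs2 by 4.34 (SE 0.40) and Tnf by 2.35 (SE 0.18). Cd40 was higher by 2.56 (SE 0.38, adjusted p = 0.00493). Cd86 was lower by a log2 difference of -1.19 (SE 0.25, adjusted p = 0.0204), Kit by -2.76 (SE 0.35, adjusted p = 0.00269) and Irf4 by -2.38 (SE 0.59, adjusted p = 0.0377). Pparg was higher by 1.92 (SE 0.18) and Spic by 3.88 (SE 0.44). In all, 843 genes were higher and 1323 lower. This comparison joins the effects of LPS and of the knockdown, and the count fell to 1054 without unstimulated replicate 3 and 1066 without knockdown replicate 3.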

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

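The tests of the shared wild-type LPS arrays, of an even loss of response, of a smaller share of dendritic cells, of an array-wide shift and of a shared batch of the arrays numbered 2 were chosen only after the result was seen.

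Some changes stood in data that the comparisons do not use: of the 1621 probes that name several genes, 36 were higher after LPS in wild-type cells, by a median log2 difference of 0.74, and 77 were lower, when every probe was tested. In the knockdown comparison 0 of them were higher and 0 lower. Of the 12146 probes that name no gene, 95 were higher and 196 lower after LPS, and 11 were higher and 3 lower in the knockdown comparison. Beside these stand the 796 higher and 1368 lower of the 19938 genes tested.

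Of the LPS-induced genes 17, such as Cd86, Fscn1 and Ccr4, were lower in knockdown cells (2 to 35 with an array left out). A response evenly weaker on the log2 scale by itself, from the same level before LPS, is argued against. Each replicate's median share was taken out. What was left of its log2 response correlated between replicates, which share no array, by 0.58 to 0.84 over all 295 induced genes. That response was counted from unstimulated wild-type cells, so a gene's difference present before LPS would repeat in the same way. An even loss joined with such differences therefore cannot be told apart from an uneven one. A loss even on the unlogged scale would take unlike log2 shares from genes of unlike induction, so the test does not cover it. Chance in the shared wild-type LPS arrays cannot be told apart from an effect: with induction taken from the arrays numbered 2 and knockdown calls from the others, 38 of 241 lower calls were induced genes, 7.88 times the 4.82 of independent lists (5 of 427 higher calls, against 8.55), but the same with induction from numbers 1 and 3 left only 4 and 0 lower calls by limma (779 and 520 at an unadjusted p under 0.05). A smaller share of dendritic cells cannot be told apart from a change within them: it would raise other cell types' markers alike, and mast cell and basophil markers were lower instead (camera adjusted p = 0.000872), but that call is lost with an estimated correlation (adjusted p = 0.42), none of the 6 lists of other cell types, this one among them, had a mean above 0 (-0.52 to -0.07), and a cell type outside the lists stays open. Retroviral infection and histidinol selection cannot be told apart from loss of JmjD2d, since 0 arrays of a control hairpin were analysed here. A candidate biological explanation, that JmjD2d is needed for part of the maturation response, therefore stays a hypothesis.

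The Kdm4d probe differed by only -0.37 between knockdown and wild-type cells. A probe reading near background is argued against, since the wild-type LPS mean of 7.69 lay above 98.8% of 1194 olfactory and vomeronasal receptor genes, which dendritic cells are not known to express, and above their 95th percentile of 6.92. Of all genes 51.3% lay at or below it. Such a rank does not measure the nonspecific signal of the Kdm4d probe itself. Whether the probe also reads other transcripts, or the hairpin acts mainly on protein, was not tested.

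Interferon genes were higher in the arrays numbered 2 of each group, by 1.13, 1.31 and 0.67 in unstimulated, LPS-treated and knockdown cells. Other lists differed too. The mean of dendritic cell markers was lower in arrays numbered 2, at 8.55, 8.42 and 8.02 in these groups. Replicates 1 and 3 had 9.61 and 9.35, 9.29 and 8.96, and 8.51 and 8.12. Inflammatory effectors were higher in unstimulated replicate 2 (10.9, against 9.84 and 9.89) but not in wild-type LPS replicate 2 (12.07, against 12.07 and 12.11). The reference genes lay a mean of 0.05 from the other replicates (0.13, 0.05 and -0.04 in unstimulated, LPS-treated and knockdown cells). This decides nothing about an array-wide shift, since normalization between arrays would already have removed one. A batch or culture shared by the arrays numbered 2 is a candidate explanation: outside the interferon list, over 19903 genes, their deviations correlated between groups by 0.12 at the lowest, although correlations over all genes had been seen before. No biological explanation was tested, since the design names none for the replicate number.

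The real grouping of 6 arrays called 2164 genes for LPS, 152 for the knockdown and 2166 for LPS-treated knockdown against unstimulated cells. In each, 1 of the 10 splits, the real one, gave as many, and the highest other split gave 0 by limma, including among the 4 splits that part all pairs. A share of splits under 0.05 cannot be reached with 10 splits.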

How the results depend on the processing

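The tests with the arrays numbered 2 left out were chosen only after the result was seen. Each count moved as follows where it moved by more than 1.5 times, and the cause was not tested unless the setting itself gives it. Array weights (0.248 to 6.83) gave 4155 genes higher and 4302 lower after LPS, 2058 higher and 2225 lower in knockdown, and 5037 in LPS-treated knockdown against unstimulated wild-type cells. They also gave 127 LPS-induced genes lower and 17 higher, a median share kept of 85.6%, 2 lists higher and 9 lower in knockdown, and a Kdm4d knockdown minus wild-type difference of -0.34 with an adjusted p of 0.0131 (0.155 to 0.591 under the other alternatives). Fitting only the groups compared, with fewer arrays, gave 14 higher and 19 lower in knockdown, 8 LPS-induced genes lower and 2 lists higher. Testing all probes, a larger family, gave 48 higher and 43 lower, 9 LPS-induced genes lower, 3 lists lower after LPS, and 2 lists higher and 13 lower in knockdown. Quantile normalization gave 111 lower in knockdown, and the dim-gene filter 9 lists lower. The replicate block gave 301 higher and 247 lower, 37 LPS-induced genes lower and 5 higher, and 9 lists lower in knockdown. It changed no other call of a difference printed above, apart from the values given beside results. A 2-fold minimum leaves fewer genes by construction, 295 and 240 after LPS and 22 and 31 in knockdown. Induction of 4-fold leaves 81 genes, 2 of them lower, with 95.2% kept. Adjustment over the induced genes alone gave 36 lower and 7 higher. With an estimated correlation 0 lists were called in either direction of either comparison, where the preset correlation called 7 higher and 1 lower after LPS. Fry called 2 lists lower after LPS, and 0 higher and 1 lower in knockdown. Without the arrays numbered 2, counts were 1757 and 3152 after LPS, 427 and 241 in knockdown, 3803 for the third comparison, 57 and 5 among LPS-induced genes, and 2 lists higher and 10 lower. Leaving out each array in turn gave 393 to 1246 higher and 475 to 2178 lower after LPS, 11 to 257 higher and 7 to 126 lower in knockdown, and 1054 to 2602 for the third comparison. It gave 208 to 323 induced genes, 2 to 35 of them lower and 0 to 2 higher, a share kept of 85.7% to 94.2%. It gave a Kdm4d difference of -0.45 to -0.27, 7 to 9 lists higher and 1 to 2 lower after LPS, and 1 to 4 higher and 5 to 11 lower in knockdown. The knockdown counts (higher and lower) were 45 and 49 without unstimulated replicate 1, 33 and 42 without unstimulated replicate 3, 12 and 14 without wild-type LPS replicate 1, 257 and 126 without replicate 2 and 11 and 7 without replicate 3, and 44 and 76, 49 and 41, and 14 and 16 without knockdown replicates 1, 2 and 3. After LPS they were 491 and 550 without unstimulated replicate 1, 393 and 544 without unstimulated replicate 3, 487 and 575, 1246 and 2178, and 416 and 475 without LPS replicates 1, 2 and 3. For LPS-treated knockdown against unstimulated wild-type cells they were 1238 and 1054 without unstimulated replicates 1 and 3 and 1066 without knockdown replicate 3. LPS-induced genes lower in knockdown were 10 without unstimulated replicate 1, 3, 35 and 2 without wild-type LPS replicates 1, 2 and 3, and 7 and 6 without knockdown replicates 2 and 3. Lists lower in knockdown were 8 and 9 without wild-type LPS replicates 1 and 2, and 11 and 8 without knockdown replicates 1 and 3. Lists higher in knockdown were 2 without unstimulated replicate 2, 3 and 2 without wild-type LPS replicates 2 and 3, and 2, 2 and 4 without knockdown replicates 1, 2 and 3. Lists lower after LPS were 2 without unstimulated replicate 3. Of 91 named LPS changes 82 passed under all alternatives other than left-out arrays and 61 under all, and of 33 named knockdown changes 7 and 4 did. The sign turned in 8 values of genes that passed no test: Kdm4c LPS minus unstimulated, -0.02, read 0.07 with array weights, 0.08 after quantile normalization, 0.1 without unstimulated replicate 1 and 0.02 without LPS replicate 2 (-0.12 to 0.1 with each array left out). Kdm4c knockdown minus wild-type read -0.01 without the arrays numbered 2. Gusb knockdown minus wild-type, -0.13, read 0.06 with array weights, 0.03 without knockdown replicate 2 and 0.08 without the arrays numbered 2 (-0.24 to 0.03 with each array left out). The share of LPS changes that were rises was 36.8% as deposited, 40.6% after quantile normalization and 31.8% after centring, and that of knockdown changes 52.6%, 45.6% and 48.1%.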

Other observations

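The tests of the fatty acid oxidation list were chosen only after the result was seen, since 3 of its members were already known to be higher; the list of PPARg targets was chosen once Pparg had been seen to be higher, before the values of its members were seen. No other such list was tried.

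Of 27 measured genes of fatty acid oxidation 25 had positive differences in the knockdown cells, with a median log2 difference of 0.43. Acaa2, a mitochondrial thiolase (1.26, SE 0.15, n = 3 against 3, limma adjusted p = 0.0145), Ech1, an isomerase of unsaturated fatty acids (0.85, SE 0.10, adjusted p = 0.0158), and Pex10, a peroxisome biogenesis factor (1.22), rose over all genes; 14 rose adjusted over the list alone and 6 in the paired fit. Acads, the short-chain dehydrogenase, was at 0.92 (adjusted p = 0.0578; 0.0259 in the paired fit), and Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, at 0.89 (adjusted p = 0.0771; 0.0436 in the paired fit). Without Acaa2, Ech1 and Pex10, which had been seen beforehand, 22 of 24 members had positive differences, with a median of 0.39. Of these 24, limma called 0 over all genes, 10 adjusted over the list alone and 3 in the paired fit, and camera gave p = 5.85e-13 (p = 0.0372 with an estimated correlation).

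A hypothesis is that higher Pparg may raise its target genes. Of 20 measured PPARg targets 11 had positive differences, with a median of 0.03; limma called 0 over all genes, 6 adjusted over the list alone and 4 in the paired fit, and camera gave p = 0.00285 for a higher list (p = 0.0235 with an estimated correlation). The 6 members that pass over the list alone are Nr1h3, an oxysterol receptor (1.07, adjusted p = 0.149; 0.0345 in the paired fit), Angptl4, an inhibitor of lipoprotein lipase (1.06, adjusted p = 0.0995), Plin2, a lipid droplet coat protein (0.95, adjusted p = 0.0636; 0.0128), Adipor2, an adiponectin receptor (0.88, adjusted p = 0.0773; 0.0238), Abcg1, a cholesterol exporter (0.62, adjusted p = 0.144; 0.0439), and Fabp5, a fatty acid binding protein (0.23, adjusted p = 0.225). Fabp4, a classical target, was at 0.05, Lpl, a lipase, at -0.01 and Pltp, a phospholipid transfer protein, at -1.02. The members went both ways, so the median of the list decides nothing, and the cell composition weighed for the maturation genes was not excluded here either.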
